A study of Mus musculus with 15 samples.

How the data were processed

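The deposited table gave a value for 18536 genes in each of 15 libraries of mouse auditory nerve, 3 per age (P3, P7, P14, P21 and adult). Per the labels, the nerve was microdissected, both cochleae of a mouse were pooled, total RNA was purified with the miRNeasy kit, samples of low quality on the Bioanalyzer were left out, and libraries were made with the TruSeq kit. Neither sex, litter nor library date was stated. Per the submitters' processing notes, the reads were handled with Partek, TopHat2 and DESeq2 on build mm10. The annotation, the counting settings, the use of strand and any filter were not stated.

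The per-library signal is, as deposited, a read count per gene divided by 1 size factor per library, called a normalized read count here. The signal was read as such because 99.94% of positive values were whole multiples of 1 step per library within a tolerance of 0.1. Each step, between 0.843 and 1.22, is the value of 1 read. Dividing by the step recovered between 35250155 and 42258738 reads per library. A floor of 3 reads corresponded to a normalized count between 2.53 and 3.65. Reads without molecular identifiers are not independent molecules, so the floor covers counting error only. No gene had fewer than 10 recovered reads in total, and 0 mitochondrial genes were present. The authors' table also holds, per the file headers, a p-value, a step-up FDR and a signed fold change for each pair of the 4 postnatal ages. Those adjusted p-values were used only for the counts given as the authors'.

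Symbols were compared with GENCODE M21: 18202 of 18536 matched, 18181 of these on the same chromosome and 18175 overlapping. Starts were identical for 6740 and ends 1 less than the table's stop for 6561, so ends are printed 1 below the stop.

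The design written beforehand named edgeR for read counts and limma for normalized values. Since the table holds normalized values, limma (3.58.1, R 4.3.3) was used with a trend and robust empirical Bayes on log2(value + 1). Genes with a value of at least 10 in at least 3 libraries were tested, 16723 in all. All 15 libraries entered 1 fit with 10 residual degrees of freedom and no covariate. Comparisons were P7 against P3, P14 against P7, P21 against P14, adult against P21, adult against P3, and all 5 ages jointly, each called at a Benjamini-Hochberg adjusted p under 0.05 (two-sided). A gene rose or fell when it was called.

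Marker lists, 35 in all, were fixed with their members before the data were examined, as were the tests, the comparisons and most alternatives. Each list was tested with camera at a preset correlation of 0.01, adjusted over the 35 lists of a comparison, with an estimated correlation, and with fry, which asks only whether a list's genes move one way on balance. Members absent from the table or below the filter were not analysed here.

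Genes were named by a fixed rule. It took the 5 that rose and the 5 that fell most among called genes with at least 10 CPM, taken from the normalized counts, in the higher age, no predicted symbol and no overlap between the libraries of both ages. It also allowed up to 4 members per list with the smallest adjusted p, and 25 genes chosen beforehand. Some genes that the rule allows are not reported here. Paralogs with near-identical sequences can share reads: the globins, Bglap and Bglap2, Tgtp1, the H2 genes, C4b and ribosomal proteins.

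Alternatives were quantile normalization, no filter, a filter of 50, pseudocounts of 0.1 and 10, a minimal log2 fold change of 1, only both ages in the fit, DESeq2 (1.42.0) and limma-voom on the recovered reads, each library left out in turn, and the replicate number as a block. After the data were seen, edgeR (4.0.16) on the recovered reads, TMM scaling and a fit without the 4 libraries low in the Y-linked gene Eif2s3y were added.

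The code was tested on simulated data with 200 changed genes in each of 5 comparisons. Limma recovered between 34.3% and 50.7% of changes of 1.5-fold, between 68.7% and 73.1% of 2-fold and between 86.4% and 95.5% of 4-fold, with between 2.99% and 6.04% false calls. DESeq2 made between 15.3% and 24.6% false calls. A list of 16 genes raised 2-fold was called by camera, with either correlation, and by fry in all 5. Of the other 34 lists camera and fry each called 1 in 1 comparison and 0 in the rest. The simulated genes were drawn independently of one another, so these list calls could not test the preset correlation of 0.01. In the libraries the estimated correlation was 0.38 for the peripheral myelin list and 0.72 for the cell cycle list.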

Results

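Transcript levels were measured by bulk RNA sequencing in the auditory nerve of mice, dissected out of the cochlea at postnatal day (P) 3, P7, P14 and P21 and in adults. The 15 libraries comprised 3 per age, each from both cochleae of 1 mouse. The floor of detection, 3 reads, corresponded to a normalized count between 2.53 and 3.65. Of 16723 genes tested over the 5 ages, 14274 (85.4%) differed between ages at a limma adjusted p under 0.05. The first principal component of the log2 values held 57.3% of the variance and the second 14.6%. The dissections also held transcripts of other tissue. Col1a2, a fibrillar collagen, was the most abundant gene in each P3 library and Coch in each P21 library. Tectb, a tectorin of the tectorial membrane, stood between 117860 and 207220 at P7. Shares of tissue were not measured, so a change in them was not told apart from a change within cells for any list. Gene levels are given as normalized read counts, mean ± SD over the 3 libraries of an age, and fold changes on the log2(value + 1) scale with their standard error (SE). Coordinates are those of the deposited table for mouse build mm10, each spanning the whole gene. The Y-linked gene Eif2s3y was low in 4 libraries (P14 replicate 1, P21 replicates 1 and 2 and adult replicate 3), and 1 alternative left them out together, which left P21 with 1 library. The same 4 were high in Xist, a transcript of females (24200 to 44400 normalized counts). All P3 and P7 libraries had the male pattern. Sex, which was not a covariate, therefore goes partly with age in every comparison except P7 against P3. Genes named for going against the direction of their list were chosen after their values were seen.

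**Figure D1:**
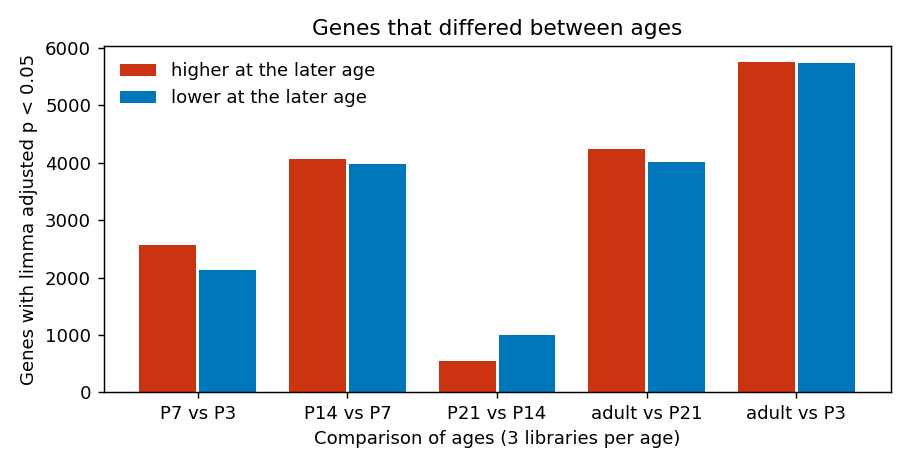
Number of genes (vertical axis) with a limma adjusted p under 0.05 in each comparison of ages (horizontal axis), as red bars for genes higher at the later age and blue bars for genes lower at the later age. From P14 to P21, 550 genes were higher and 1003 lower, against 4065 and 3983 from P7 to P14.

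The comparison of P7 with P3 asked which transcripts changed over the end of the first postnatal week. Pmp22, a structural protein of compact peripheral myelin (chromosome 11, 63128982 to 63159547), went from 63320 ± 12732 to 267108 ± 34108 normalized counts, a 4.26-fold rise (log2 fold change 2.09 ± 0.15 SE, adjusted p = 1.93e-06, n = 3 per age, limma). Ifi44, an interferon-induced gene (chromosome 3, 151730923 to 151749959), fell from 1200 ± 377 to 54.9 ± 14.2, and Cd74, the invariant chain of class II antigen presentation (chromosome 18, 60803849 to 60812652), from 3613 ± 1909 to 316 ± 40.7. Their log2 fold changes were -4.41 ± 0.30 SE (adjusted p = 1.89e-06) and -3.32 ± 0.42 SE (adjusted p = 0.000129). In all, 2568 genes rose and 2135 fell, 950 of the 4703 by at least 2-fold.

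Among genes with a higher mean of at least 10 CPM and no overlap between the 3 libraries of each age, the 5 that rose most were Tmprss9, Mog, Otos, Ermn and Mobp. Tmprss9, a transmembrane serine protease, rose 26.4-fold to 16557 ± 3718, and Otos, a secreted protein of cochlear fibrocytes, 13.9-fold to 46303 ± 5926. Mog, Ermn and Mobp are proteins of oligodendrocytes, the myelinating cells of the central part of the nerve, and rose by 4.37 ± 0.96, 3.66 ± 0.91 and 3.47 ± 0.87 (log2 ± SE). Mog stood at 147, 31.3 and 60.3 in the P3 libraries and at 1790, 2830 and 517 in the P7 libraries, replicates 4, 5 and 6. For Mobp the adjusted p ranged from 0.00032 to 0.0518 (without P7 replicate 5) over the alternatives run. The 5 that fell most were Serpina3f, a protease inhibitor (-6.11 ± 0.91), Nlrc5, the transactivator of class I antigen presentation (-5.76 ± 0.45), Zbp1, an interferon-induced nucleic acid sensor (-4.85 ± 0.58), Col10a1, the collagen of hypertrophic cartilage (-4.69 ± 0.89), and Tgtp1, an interferon-induced GTPase (-4.58 ± 0.29). Tgtp1 has a near-identical paralog, so its reads may be split between both. Without P7 replicate 6 the log2 fold change was 5.08 (Mog), 4.35 (Ermn) and 4.23 (Mobp), and without P3 replicate 1 it was 4.07 (Mobp) and -6.4 (Nlrc5).

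Of 20 peripheral myelin genes, 15 rose, 0 fell and 5 were not called (17 and 0 adjusted over the list alone). The list rose (camera adjusted p = 2.69e-13, 0.46 with an estimated correlation), with Gjb1, the connexin of Schwann cells, up 3.98-fold and Cd9 up 3.04-fold. Several of its members, such as Mbp (3.33-fold), are also made by oligodendrocytes. Of the 15 oligodendrocyte genes, 6 rose, 0 fell and 9 were not called (9 and 0 adjusted over the list alone), and the list rose too (camera adjusted p = 0.00164, 0.807 with an estimated correlation). Enzymes of cholesterol biosynthesis rose, 15 of 19 (16 adjusted over the list alone; camera adjusted p = 7.71e-09, 0.586 with an estimated correlation), among them Msmo1 (log2 1.15 ± 0.11) and Hmgcs1 (log2 0.95 ± 0.11). Of 27 genes of the mitochondrial respiratory chain, 14 rose and 0 fell (15 and 0 adjusted over the list alone; camera adjusted p = 1.47e-07, 0.805 with an estimated correlation), such as Uqcrc2 (log2 0.69 ± 0.09) and Ndufs1 (log2 0.62 ± 0.08).

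All 14 measured genes of antigen presentation fell, also when adjusted over the list alone (camera adjusted p = 2.7e-11, 0.46 with an estimated correlation). Ciita, the transactivator of class II genes, fell 25.1-fold and Psmb9, an immunoproteasome subunit, 7.81-fold. Of 15 interferon response genes, 14 fell and 0 rose (15 and 0 adjusted over the list alone; camera adjusted p = 2.69e-13, 0.46 with an estimated correlation), with Isg15 down 12.3-fold. In the macrophage list, 10 of 21 fell and 2 rose (10 and 2 adjusted over the list alone; camera adjusted p = 0.00333, 0.807 with an estimated correlation): Cd68 fell (log2 -1.32 ± 0.25), while Cd14 (log2 0.57 ± 0.13) and Tmem119 (log2 0.60 ± 0.21) rose. For Tmem119 the adjusted p was between 0.0546 and 0.16 without any 1 of P3 replicates 1 and 3, P7 replicates 4, 5 and 6, P14 replicate 1 and adult replicates 1, 2 and 3. It was 0.0693 with quantile normalization and ranged from 0.0171 to 0.16 over the alternatives run. For Tmem119 the adjusted p was 0.0536 without the 4 libraries low in Eif2s3y. Osteoclast genes fell, 5 of 10 (6 adjusted over the list alone; camera adjusted p = 0.000246, 0.586 with an estimated correlation), for example Ctsk, the cathepsin of bone resorption (log2 -1.40 ± 0.21). Fibroblast and matrix genes fell as a list, 10 of 21 against 2 that rose (11 and 2 adjusted over the list alone; camera adjusted p = 0.00251, 0.805 with an estimated correlation). Col12a1 fell (log2 -2.03 ± 0.31), while the proteoglycans Dcn (log2 0.80 ± 0.07) and Lum (log2 0.65 ± 0.11) rose. Cell-cycle genes fell, 10 of 23 (12 adjusted over the list alone; camera adjusted p = 6.18e-05, 0.807 with an estimated correlation), Mcm4 (log2 -0.60 ± 0.10). Genes of axon growth and guidance fell, 7 of 27 (6 adjusted over the list alone; camera adjusted p = 0.00571, 0.805 with an estimated correlation), Dcx (log2 -1.36 ± 0.23) and L1cam (log2 -1.09 ± 0.17). Spiral ganglion neuron genes went both ways, 8 up and 5 down of 24 (8 and 5 adjusted over the list alone; camera adjusted p = 0.538), and Pvalb rose (log2 1.31 ± 0.13).

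Under the other alternatives run, the adjusted p of these 11 lists lay between 9.42e-18 and 0.1. Without P3 replicate 3 the number of genes called was 3124, and without P7 replicate 5 it was 3080. The 3 libraries of each age did not overlap in 54.2% of genes, against 10% by chance, and the authors' deposited table has 2898 genes higher and 2658 lower at P7 at an adjusted p under 0.05.

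The interval from P7 to P14 spans the onset of hearing. Slc17a7, the vesicular glutamate transporter of spiral ganglion neurons (chromosome 7, 45163921 to 45176139), rose 4.73-fold from 3624 ± 215 to 17135 ± 1115 normalized counts (log2 fold change 2.24 ± 0.13 SE, adjusted p = 3.58e-08, n = 3 per age, limma). The voltage-gated sodium channel gene Scn8a, whose product sits at nodes of Ranvier (chromosome 15, 100870645 to 101045938), rose 5.27-fold from 1155 ± 56.4 to 6108 ± 612 (log2 fold change 2.40 ± 0.19 SE, adjusted p = 4.23e-07), and the neurofilament gene Nefh 4.49-fold to 83595 ± 4408. Top2a, a topoisomerase of dividing cells (chromosome 11, 98992947 to 99024189), fell from 2262 ± 95.6 to 462 ± 237 (log2 fold change -2.44 ± 0.63 SE, adjusted p = 0.00604). In this comparison 4065 genes rose and 3983 fell, 2413 of the 8048 by at least 2-fold.

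The 5 genes that rose most by the same rule were Ceacam16, Etnppl, Cox8b, Vwa7 and Hapln4. Ceacam16, a glycoprotein of the tectorial membrane (chromosome 7, 19852097 to 19861299), went from 87.5 ± 27.6 to 53013 ± 15452 (log2 fold change 9.23 ± 0.29 SE, adjusted p = 1.06e-09). Etnppl, a phospho-lyase, rose (log2 4.41 ± 0.75), Cox8b, a subunit of cytochrome c oxidase, (log2 4.26 ± 0.39), Vwa7 (log2 3.99 ± 0.20) and Hapln4, a hyaluronan link protein of axonal matrix, (log2 3.74 ± 0.22). The 5 that fell most were Tecta (-7.31 ± 0.52) and Tectb (-6.22 ± 0.24, both log2 ± SE), the tectorins of the tectorial membrane, and the osteoclast genes Acp5 (-6.12 ± 0.69), Mmp9 (-6.05 ± 0.62) and Atp6v0d2 (-5.70 ± 0.51). Ceacam16, Tecta and Tectb belong to the list of cochlear epithelium, in which 4 genes rose and 7 fell (camera adjusted p = 0.162). Without P7 replicate 6 the log2 fold change was 5 (Etnppl), without P14 replicate 2 it was -5.1 (Acp5) and -5.07 (Mmp9), and without P14 replicate 3 it was -6.88 (Acp5), -6.79 (Mmp9) and -6.3 (Atp6v0d2).

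Of 24 spiral ganglion neuron genes, 19 rose, 1 fell and 4 were not called (21 and 1 adjusted over the list alone). The list rose (camera adjusted p = 5.76e-08, 0.446 with an estimated correlation), with Snap25 up 5.79-fold and Thy1 up 4.29-fold, while Gata3, a transcription factor of inner ear neurons, fell (log2 -1.33 ± 0.26). Among 11 genes that mark subtypes of type I neurons, 10 rose and 0 fell (the same counts adjusted over the list alone; camera adjusted p = 2.26e-06, 0.306 with an estimated correlation), such as Lypd1 (log2 2.79 ± 0.13), a cell surface protein. Genes of the node of Ranvier and paranode rose, 20 of 29 against 2 that fell (21 and 2 adjusted over the list alone; camera adjusted p = 2.19e-07, 0.71 with an estimated correlation). The sodium channel subunit Scn4b rose 8.07-fold, and Nrcam (log2 -0.57 ± 0.16) and Epb41l2 (log2 -0.67 ± 0.12) fell. For synaptic vesicle and release genes the counts were 16 up and 2 down of 20 (17 and 2 adjusted over the list alone; camera adjusted p = 2.19e-07, 0.668 with an estimated correlation), with Syt2, a calcium sensor of fast release, up 6.67-fold and Stx1a (log2 -0.73 ± 0.11) and Cplx2 (from 2508 ± 78.9 to 1279 ± 323) down. For Cplx2 the adjusted p was 0.054 without P7 replicate 4, 0.0615 without P7 replicate 5, 0.0513 without P7 replicate 6 and 0.101 without P14 replicate 2. It ranged from 0.000348 to 0.101 over the alternatives run. For Cplx2 the adjusted p was 0.0556 without the 4 libraries low in Eif2s3y. Potassium and HCN channel genes rose, 10 against 2 of 20 (11 and 2 adjusted over the list alone; camera adjusted p = 0.00527, 0.71 with an estimated correlation): Hcn2 rose 7.02-fold, and Kcna4 fell (log2 -1.10 ± 0.21). Respiratory chain genes rose, 17 of 27 (18 adjusted over the list alone; camera adjusted p = 1.39e-05, 0.71 with an estimated correlation), Sdha (log2 0.84 ± 0.05). Endothelial genes rose, 9 of 15 with 1 down (the same counts adjusted over the list alone; camera adjusted p = 0.019, 0.71 with an estimated correlation), such as Abcb1a (log2 1.26 ± 0.14), and so did interferon response genes, 6 of 15 (8 adjusted over the list alone; camera adjusted p = 0.0147, 0.935 with an estimated correlation), such as Ifit1 (log2 1.73 ± 0.29).

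All 23 cell-cycle genes fell, also when adjusted over the list alone (camera adjusted p = 1.02e-06, 0.71 with an estimated correlation), Cdk1 5.27-fold and Tyms 3.17-fold. The erythroid, neutrophil and B lymphoid lists, which mark marrow-derived cells, had camera adjusted p-values of 0.811, 0.252 and 0.358, and the erythroid mean lay between 6.9 and 8.35 at P7 and between 6.48 and 8.99 at P14. All 10 osteoclast genes fell, likewise adjusted over the list alone (camera adjusted p = 2.31e-06, 0.446 with an estimated correlation). Of 22 genes of cytosolic ribosomal proteins, which have many pseudogene copies, 20 fell and 0 rose (the same counts adjusted over the list alone; camera adjusted p = 5.57e-08, 0.71 with an estimated correlation), Rplp0 (log2 -1.12 ± 0.08). Fibroblast and matrix genes fell, 13 of 21 with 1 up (the same counts adjusted over the list alone; camera adjusted p = 0.000884, 0.71 with an estimated correlation), Col3a1 (log2 -1.18 ± 0.20) and Lum (log2 -1.49 ± 0.11). Axon growth and guidance genes fell as a list, 13 of 27 against 3 (13 and 4 adjusted over the list alone; camera adjusted p = 0.0147, 0.714 with an estimated correlation). Gap43, a growth cone protein, fell 5.95-fold and Robo2, a guidance receptor, 3.98-fold, while L1cam (log2 1.30 ± 0.17), Plxna4 (log2 0.98 ± 0.22) and Crmp1 (log2 0.65 ± 0.19) rose. For Crmp1 the adjusted p ranged from 0.000918 to 0.0646 (without P7 replicate 6) over the alternatives run. For Crmp1 the adjusted p was 0.0504 without the 4 libraries low in Eif2s3y. Peripheral myelin genes were not called as a list by camera (7 up, 1 down of 20, adjusted p = 0.0975), while fry called them higher (adjusted p = 0.0426). The member that fell was Pmp2, the myelin fatty acid binding protein (log2 -2.82 ± 0.42). Under the other alternatives run, the adjusted p of these 13 lists lay between 6.54e-11 and 0.0448. The 3 libraries of each age did not overlap in 61.4% of genes, against 10% by chance, and the authors' deposited table has 4289 genes higher and 4187 lower at P14 at an adjusted p under 0.05.

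**Figure D2:**
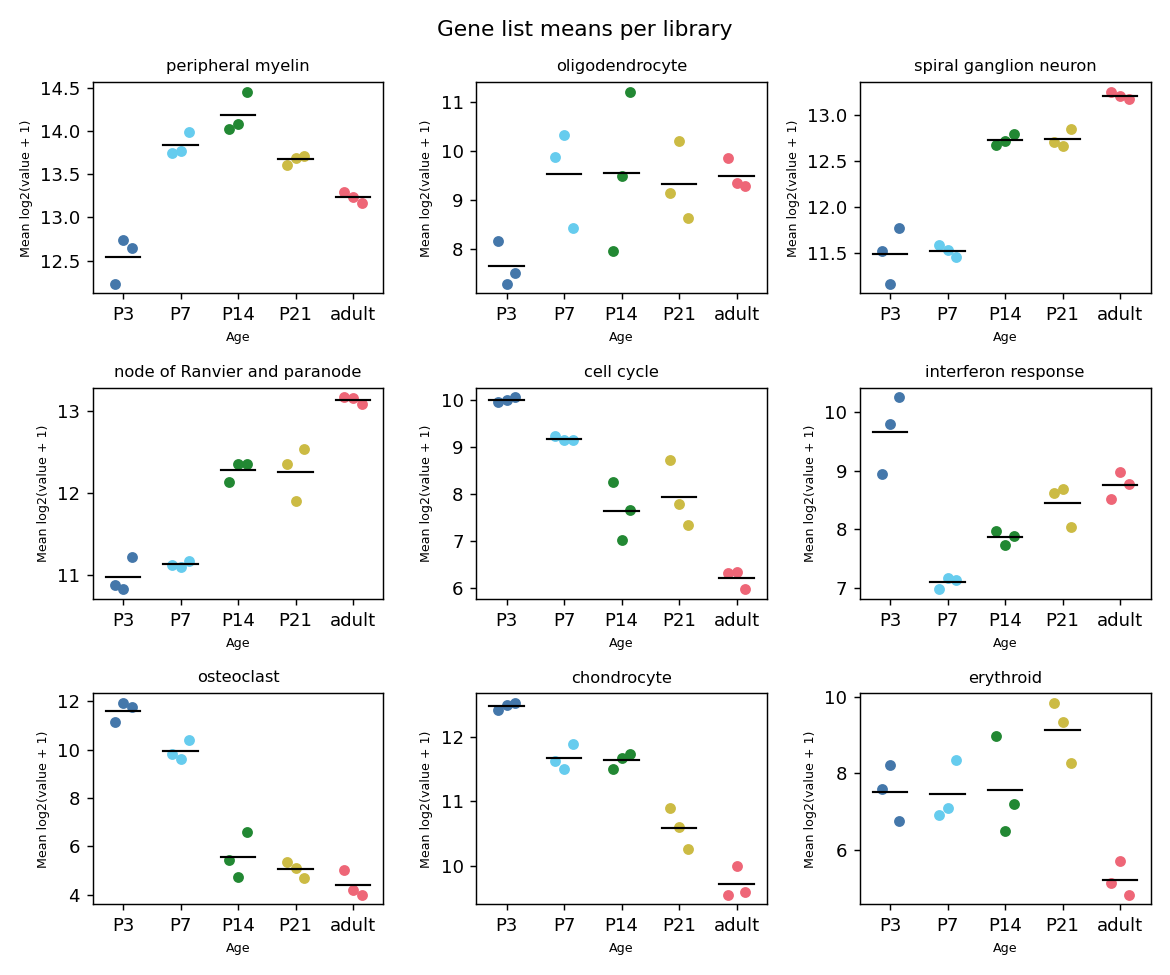
Mean of log2(normalized count + 1) over the genes of 9 lists (vertical axes) in each library (points), by age (horizontal axes), with black lines at the mean of the 3 libraries of an age. The osteoclast means lay between 9.62 and 11.94 at P3 and P7 and between 3.99 and 6.59 from P14 on, and the oligodendrocyte means at P14 spread from 7.97 to 11.21.

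Between P14 and P21 fewer genes were called than in the other comparisons. Col9a1, a collagen of cartilage and of the cochlea (chromosome 1, 24177610 to 24252738), fell 8.45-fold from 64430 ± 9366 to 7600 ± 761 normalized counts (log2 fold change -3.08 ± 0.13 SE, adjusted p = 5.48e-08, n = 3 per age, limma). Pmp22 fell 1.77-fold from 241594 ± 25547 to 137125 ± 19559 (log2 fold change -0.82 ± 0.15 SE, adjusted p = 0.00534). For Pmp22 the adjusted p was 0.0578 with quantile normalization and 0.203 without the 4 libraries low in Eif2s3y, the highest over the alternatives run, and the lowest was 4.63e-06. Ibsp, a sialoprotein of bone matrix (chromosome 5, 104299287 to 104311472), fell 9.34-fold from 50092 ± 15186 to 6059 ± 4327 (log2 fold change -3.22 ± 0.38 SE, adjusted p = 0.00041). In all, 550 genes rose and 1003 fell, 312 of the 1553 by at least 2-fold.

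The 5 genes that rose most were the membrane transporter Slc4a11 (2.62 ± 0.27), the dipeptidase Cndp1 (1.88 ± 0.47), Plbd1 (1.78 ± 0.46), the thyroxine carrier Ttr (1.65 ± 0.39) and the lubricating proteoglycan Prg4 (1.63 ± 0.38). For Cndp1 the adjusted p was 0.124 without P14 replicate 3 and 0.0812 without P21 replicate 3. It ranged from 0.00103 to 0.124 over the alternatives run. For Plbd1 the adjusted p was 0.136 without P14 replicate 3, 0.0744 without P21 replicate 2 and 0.0789 without P21 replicate 3. It ranged from 0.00053 to 0.136 over the alternatives run. For Ttr the adjusted p was 0.0596 without P14 replicate 1, 0.0705 without P14 replicate 2 and 0.0522 without P21 replicate 2. It ranged from 0.00058 to 0.251 over the alternatives run. For Prg4 the adjusted p was 0.0533 without P14 replicate 1 and 0.0648 without P14 replicate 2. It ranged from 0.000314 to 0.287 over the alternatives run. The 5 that fell most were Oc90, an otoconin (-4.01 ± 0.25), Umodl1 (-3.84 ± 0.69), Tmprss9 (-3.49 ± 0.27), Ibsp and the citrate transporter Slc13a5 (-3.08 ± 0.41, all log2 ± SE). For Cndp1, Ttr, Prg4 and Umodl1 the adjusted p was 0.0967, 0.251, 0.287 and 0.0853 without the 4 libraries low in Eif2s3y, and over the alternatives run it ranged from 4.98e-11 to 0.0853 (Umodl1). Without P21 replicate 1 the log2 fold change of Umodl1 was -3.09.

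Of 15 basement membrane genes, 0 rose, 11 fell and 4 were not called (0 and 13 adjusted over the list alone). The list fell (camera adjusted p = 2.81e-10, 0.459 with an estimated correlation), with Nid1 down 2.25-fold and Col4a2 down 2.52-fold. Fibroblast and matrix genes fell, 9 of 21 with 0 up (14 and 1 adjusted over the list alone; camera adjusted p = 1.12e-08, 0.459 with an estimated correlation), Col3a1 3.25-fold and Col1a2 2.98-fold. In the osteoblast and osteocyte list, 9 of 15 fell (13 adjusted over the list alone; camera adjusted p = 7.75e-08, 0.537 with an estimated correlation), while Spp1, also made outside bone, rose (log2 0.84 ± 0.16). Chondrocyte genes fell, 7 of 16 (8 adjusted over the list alone; camera adjusted p = 6.02e-08, 0.218 with an estimated correlation), among them Col2a1 (log2 -2.40 ± 0.19) and Col9a2 (log2 -1.80 ± 0.10). Of 20 peripheral myelin genes, 7 fell and 0 rose (12 and 0 adjusted over the list alone; camera adjusted p = 5.38e-07, 0.466 with an estimated correlation). Macrophage genes fell, 7 of 21 (14 adjusted over the list alone; camera adjusted p = 6.47e-05, 0.762 with an estimated correlation), such as Tmem119 (log2 -1.20 ± 0.21). Immature and non-myelinating Schwann cell genes fell as a list (2 of 16, the same number adjusted over the list alone; camera adjusted p = 0.0214, 0.459 with an estimated correlation): the members called were Mia (log2 -1.84 ± 0.26) and Id2 (log2 -0.56 ± 0.09). In the axon growth and guidance list the member that fell was Dpysl3 (log2 -0.73 ± 0.12; 1 of 27, also adjusted over the list alone; camera adjusted p = 0.0253, 0.83 with an estimated correlation). For the immature Schwann cell list the adjusted p was 0.0589 without P14 replicate 3, 0.0594 without P21 replicate 1 and 0.105 without P21 replicate 2. It ranged from 0.00464 to 0.459 over the alternatives run. For the axon growth list the adjusted p was 0.105 without P14 replicate 3 and 0.352 without P21 replicate 2. It ranged from 0.00337 to 0.83 over the alternatives run. For the immature Schwann cell list, the axon growth list, Dpysl3 and Spp1 the adjusted p was 0.17, 0.361, 0.0521 and 0.0946 without the 4 libraries low in Eif2s3y, and over the alternatives run it ranged from 1.11e-06 to 0.0521 (Dpysl3) and 3.29e-05 to 0.0946 (Spp1).

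Hair cell genes rose, 3 of 19 (5 adjusted over the list alone; camera adjusted p = 3.3e-05, 0.546 with an estimated correlation): Myo7a (log2 1.16 ± 0.24), Espn (log2 0.78 ± 0.20) and Lhfpl5 (log2 0.74 ± 0.13). In the interferon response list 1 of 15 rose, Ifit1 (log2 1.33 ± 0.29; 4 adjusted over the list alone; camera adjusted p = 0.000569, 0.763 with an estimated correlation). Type I neuron subtype genes rose, 2 of 11 (the same number adjusted over the list alone; camera adjusted p = 0.0365, 0.669 with an estimated correlation): Rxrg (log2 0.75 ± 0.14) and Calb2 (log2 0.63 ± 0.17). Erythroid genes rose as a list with 1 of 13 called, Car1 (log2 2.97 ± 0.83; 1 adjusted over the list alone; camera adjusted p = 0.000493, 0.762 with an estimated correlation). Camera also called the cell cycle (camera adjusted p = 0.0253, 0.83 with an estimated correlation), the neutrophil and marrow myeloid (camera adjusted p = 0.0253, 0.83 with an estimated correlation) and the mitochondrial respiratory chain list (camera adjusted p = 0.00812, 0.83 with an estimated correlation) as higher. The limma test called 0 of their 23, 13 and 27 genes, also adjusted over the list alone, 2, 1 and 2 had an unadjusted limma p under 0.05, DESeq2 called 0, 0 and 1, and edgeR 0, 0 and 0. The cell cycle and marrow lists differed between libraries of one age: at P21 the cell-cycle mean was 8.72, 7.78 and 7.33 in replicates 1, 2 and 3 and the erythroid mean 9.85, 9.34 and 8.26. For the cell cycle list the adjusted p was 0.732 without P14 replicate 2 and 0.981 without P21 replicate 1. It ranged from 3.9e-05 to 0.981 over the alternatives run. For the neutrophil list the adjusted p was 0.198 without P14 replicate 2, 0.116 without P14 replicate 3, 0.463 without P21 replicate 1 and 0.0501 without P21 replicate 2. It ranged from 0.000249 to 0.83 over the alternatives run. For the respiratory chain list the adjusted p was 0.0914 without P14 replicate 3 and 0.63 without P21 replicate 2. It ranged from 3.25e-05 to 0.83 over the alternatives run. For the type I neuron list the adjusted p was 0.0968 without P14 replicate 3, 0.0916 without P21 replicate 1 and 0.0907 without P21 replicate 3. It ranged from 0.0207 to 0.669 over the alternatives run. For Espn the adjusted p was 0.0769 without P14 replicate 2, 0.115 without P14 replicate 3 and 0.0773 without P21 replicate 1. It ranged from 0.00374 to 0.127 over the alternatives run. For Ifit1 the adjusted p was 0.0555 without P14 replicate 3. It ranged from 0.000166 to 0.14 over the alternatives run. For Calb2 the adjusted p was 0.13 without P14 replicate 3, 0.0581 without P21 replicate 2 and 0.068 without P21 replicate 3. It ranged from 0.00404 to 0.174 over the alternatives run. For Car1 the adjusted p was between 0.0519 and 0.148 without any 1 of P3 replicates 1, 2 and 3, P7 replicates 4, 5 and 6, P14 replicates 2 and 3, P21 replicate 1 and adult replicate 3. It ranged from 0.00728 to 0.148 over the alternatives run. For Calb2 the adjusted p was 0.174 with quantile normalization and for Car1 0.0578 with edgeR. For the interferon response list, the cell cycle list, the neutrophil list, the type I neuron list, Espn, Ifit1, Calb2, Car1 and Rxrg the adjusted p was 0.314, 0.591, 0.13, 0.0874, 0.127, 0.14, 0.132, 0.0794 and 0.0796 without the 4 libraries low in Eif2s3y, and over the alternatives run it ranged from 1.87e-05 to 0.763 (the interferon response list) and 3.76e-05 to 0.0796 (Rxrg). Under the other alternatives run, the adjusted p of these 15 lists lay between 7.1e-13 and 0.981. Without P14 replicate 1 the log2 fold change of Car1 was 3.95, without P14 replicate 2 it was 2.15, and without P21 replicate 1 it was 2.18.

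The number of genes depended on which libraries entered the fit: 979 were called without P14 replicate 2, 631 without P14 replicate 3 (24.2% of them higher at P21, against 35.4% with all libraries) and 754 without the 4 libraries low in Eif2s3y. It was 137 with only both ages in the fit (19.7% of them higher) and 2519 with DESeq2, and the authors' deposited table has 1047 genes higher and 1445 lower at P21. The 3 libraries of each age did not overlap in 24.4% of genes, against 10% by chance.

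The comparison of adults with P21 covers the time after weaning. Adult libraries were titled CTRL, not by age, and a batch of their own cannot be told apart from age. The nodal sodium channel gene Scn8a went from 7723 ± 1684 to 20841 ± 907 normalized counts, a 2.74-fold rise (log2 fold change 1.46 ± 0.19 SE, adjusted p = 0.000159, n = 3 per age, limma), and Syt2 (chromosome 1, 134646612 to 134753149) from 8991 ± 2653 to 25928 ± 2067 (log2 fold change 1.57 ± 0.24 SE, adjusted p = 0.000352). Hbb-bs, an adult beta globin (chromosome 7, 103826523 to 103827928), fell from 7698 ± 2955 to 697 ± 225 (log2 fold change -3.42 ± 0.38 SE, adjusted p = 7.11e-05), and Mki67, a marker of proliferating cells (chromosome 7, 135689788 to 135716379), from 1370 ± 1116 to 129 ± 51 (log2 fold change -3.17 ± 0.52 SE, adjusted p = 0.000514). P21 replicate 1 stood apart, Mki67 being at 2660, 717 and 736 in P21 replicates 1, 2 and 3. The log2 fold change of Mki67 was -2.55 without that library and -2.31 without the 4 libraries low in Eif2s3y. That of Hbb-bs ranged from -3.79 to -2.59 over the alternatives run. A total of 4243 genes rose and 4023 fell, 1725 of the 8266 by at least 2-fold.

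The 5 genes that rose most were Chrnb3 and Chrna6, subunits of nicotinic acetylcholine receptors, Vgf, a neuropeptide precursor, Rgs8, a regulator of G protein signalling, and Ndst4, an enzyme of heparan sulfate synthesis. Their levels differed widely between the 3 adult mice: Chrnb3 (chromosome 8, 27368711 to 27399730) stood at 1780, 24.1 and 295 in adult replicates 1, 2 and 3 and between 0 and 3.91 at P21, Chrna6 at 1370, 6.56 and 207 and between 0 and 4.89, and Vgf at 1480, 32.8 and 124 and between 6.55 and 14.4. The P21 values of Chrnb3 and Chrna6 lay at or near the floor of 3 reads, so no fold is given for them. The limma adjusted p was 0.00661 for Chrnb3, 0.0452 for Chrna6, 0.0216 for Vgf, 0.0172 for Rgs8 and 0.0194 for Ndst4. For Chrnb3 it was 0.194 without the 4 libraries low in Eif2s3y, the highest over the alternatives run, and the lowest was 4.63e-07. For Chrna6 the adjusted p was between 0.052 and 0.18 without any 1 of P3 replicates 1, 2 and 3, P7 replicates 4, 5 and 6, P21 replicates 1, 2 and 3 and adult replicates 1 and 3. It ranged from 0.000121 to 0.438 over the alternatives run. For Vgf the adjusted p was 0.056 without P21 replicate 1 and 0.102 without adult replicate 1. It ranged from 2.3e-05 to 0.198 over the alternatives run. For Rgs8 the adjusted p was 0.0789 without adult replicate 1. It ranged from 5.81e-05 to 0.162 over the alternatives run. For Ndst4 the adjusted p was 0.0604 without P21 replicate 2 and 0.0925 without adult replicate 1. It ranged from 1e-04 to 0.276 over the alternatives run. For Chrna6, Vgf, Rgs8 and Ndst4 the adjusted p was 0.438, 0.198, 0.162 and 0.276 without the 4 libraries low in Eif2s3y. Among the 5 that fell most were the red cell anion exchanger Slc4a1 (-4.56 ± 0.82), the osteocalcin paralogs Bglap2 (-4.89 ± 0.65) and Bglap (-4.80 ± 0.61), which can share reads, and the protease Ctse (-4.39 ± 0.68, all log2 ± SE). Without P21 replicate 1 the log2 fold change was -4.28 (Bglap2) and -4.15 (Bglap), and without adult replicate 2 it was -4.13 (Bglap2). Over the alternatives run it ranged from -5.01 to -3.19 (Slc4a1), from -4.94 to -3.14 (Ctse) and from -5.36 to -3.65 (Bglap).

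Of 29 genes of the node of Ranvier and paranode, 24 rose, 0 fell and 5 were not called (24 and 0 adjusted over the list alone). The list rose (camera adjusted p = 4.85e-08, 0.447 with an estimated correlation), with Cntn2 up 2.84-fold and Ank3, the anchor of nodal sodium channels, up 2.05-fold. Potassium and HCN channel genes rose, 17 of 20 with 1 down (the same counts adjusted over the list alone; camera adjusted p = 3.82e-05, 0.447 with an estimated correlation), Kcnt1 (log2 1.58 ± 0.17) and Kcnc1 (log2 1.28 ± 0.22), while Kcna4 fell (log2 -1.01 ± 0.21). Synaptic vesicle and release genes rose, 16 of 20 with 1 down (17 and 1 adjusted over the list alone; camera adjusted p = 1.48e-05, 0.447 with an estimated correlation), such as the active zone gene Bsn (log2 2.12 ± 0.27), while Stx1a fell (log2 -0.52 ± 0.11). Adult replicate 1, which had the highest Chrnb3, also had the highest mean of the potassium channel list (11.69, against 10.66 and 10.97) and of the synaptic list (13.3, against 12.85 and 12.86). Of 24 spiral ganglion neuron genes, 15 rose and 1 fell (the same counts adjusted over the list alone; camera adjusted p = 0.000848, 0.447 with an estimated correlation): Rbfox3 rose (log2 0.98 ± 0.14) and Pvalb fell (log2 -0.34 ± 0.13). For Pvalb the adjusted p was between 0.0509 and 0.203 without any 1 of P3 replicates 1 and 3, P7 replicates 4, 5 and 6, P14 replicates 2 and 3, P21 replicates 2 and 3 and adult replicates 1, 2 and 3. It was 0.0507 with TMM scaling and ranged from 0.00582 to 0.203 over the alternatives run. For Pvalb, Kcnc1 and Stx1a the adjusted p was 0.0776, 0.0565 and 0.0923 without the 4 libraries low in Eif2s3y, and over the alternatives run it ranged from 3.83e-07 to 0.0565 (Kcnc1) and 0.000264 to 0.0923 (Stx1a). The list's mean in the 3 adult libraries lay between 13.17 and 13.25.

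All 13 erythroid genes fell, and 11 of 12 B lymphoid and 10 of 13 neutrophil genes fell with them (13, 12 and 10 adjusted over the list alone). The camera adjusted p-values were 6.46e-07, 0.000148 and 0.00131, against adjusted p = 0.447, 0.447 and 0.531 with an estimated correlation. Globin genes are paralogs whose reads may be shared. Of 23 cell-cycle genes, 20 fell and 0 rose (the same counts adjusted over the list alone; camera adjusted p = 2.25e-07, 0.447 with an estimated correlation), Ube2c (log2 -3.24 ± 0.46). Osteoblast and osteocyte genes fell, 13 of 15 (14 adjusted over the list alone; camera adjusted p = 4.74e-06, 0.447 with an estimated correlation), and chondrocyte genes, 11 of 16 with 1 up (the same counts adjusted over the list alone; camera adjusted p = 0.000215, 0.447 with an estimated correlation). Col2a1 fell 6.5-fold, while Comp, a cartilage matrix protein, rose (log2 1.93 ± 0.50, from 1.54 to 2.97 over the alternatives run). Fibroblast and matrix genes fell as a list, 9 of 21 against 3 (9 and 4 adjusted over the list alone; camera adjusted p = 0.0108, 0.531 with an estimated correlation): Sparc fell 5.81-fold, and Fn1 (log2 0.81 ± 0.27), Fbln1 (log2 0.38 ± 0.13) and Col12a1 (log2 1.01 ± 0.31) rose. For Fn1 the adjusted p was 0.11 without P21 replicate 2, 0.0597 without adult replicate 1 and 0.0956 without adult replicate 3. It ranged from 0.00751 to 0.459 over the alternatives run. For Fbln1 the adjusted p was 0.101 without P21 replicate 3, 0.115 without adult replicate 1 and 0.0704 without adult replicate 3. It ranged from 0.0156 to 0.164 over the alternatives run. For Col12a1 the adjusted p was 0.072 without P21 replicate 2 and 0.0603 without adult replicate 1. It ranged from 0.00447 to 0.114 over the alternatives run. For Fn1 and Fbln1 the adjusted p was 0.0686 and 0.164 with quantile normalization. For Fn1, Fbln1, Col12a1 and the neutrophil list the adjusted p was 0.459, 0.0643, 0.114 and 0.16 without the 4 libraries low in Eif2s3y, and over the alternatives run it ranged from 1.77e-05 to 0.531 (the neutrophil list). For the fibroblast and matrix list the adjusted p was 0.0502 without P21 replicate 1. It ranged from 0.000358 to 0.531 over the alternatives run. Without P21 replicate 3 the log2 fold change of Ube2c was -3.84, and the weakest over the alternatives run was -2.06. Whether the cell-cycle genes fell because of fewer marrow-derived cells was not tested.

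Ribosomal protein genes fell, 21 of 22 (the same number adjusted over the list alone; camera adjusted p = 4.85e-08, 0.447 with an estimated correlation), Rplp0 (log2 -0.82 ± 0.08). Cholesterol biosynthesis genes fell, 14 of 19 (the same number adjusted over the list alone; camera adjusted p = 4.43e-05, 0.447 with an estimated correlation), Msmo1 (log2 -1.02 ± 0.11). Of 20 peripheral myelin genes, 8 fell and 0 rose (7 and 0 adjusted over the list alone; camera adjusted p = 0.0113, 0.531 with an estimated correlation), Pmp22 (log2 -1.20 ± 0.15). Respiratory chain genes fell as a list, 15 of 27 against 3 (16 and 3 adjusted over the list alone; camera adjusted p = 0.0108, 0.624 with an estimated correlation): Ndufa4 fell (log2 -0.77 ± 0.15) and Uqcrc1 rose (log2 0.49 ± 0.06). Macrophage genes fell, 13 of 21 (14 adjusted over the list alone; camera adjusted p = 0.000682, 0.531 with an estimated correlation), Fcer1g (log2 -1.35 ± 0.21), and complement genes, 8 of 17 with 1 up (the same counts adjusted over the list alone; camera adjusted p = 0.0108, 0.447 with an estimated correlation). C1qb fell (log2 -0.85 ± 0.19), while C4b, which has a close paralog, rose (log2 1.41 ± 0.24). For C1qb, the macrophage list and the complement list the adjusted p was 0.162, 0.109 and 0.083 without the 4 libraries low in Eif2s3y, and over the alternatives run it ranged from 9.2e-05 to 0.162 (C1qb), 5.61e-05 to 0.531 (the macrophage list) and 0.00369 to 0.447 (the complement list). Immediate early genes, which respond to dissection, fell, 8 of 14 with 1 up (8 and 2 adjusted over the list alone; camera adjusted p = 0.0135, 0.447 with an estimated correlation), Nr4a1 (log2 -1.51 ± 0.17).

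Among cochlear cell markers, hair cell genes fell in 12 of 19 cases (12 down and 1 up adjusted over the list alone; camera adjusted p = 0.000274, 0.447 with an estimated correlation), for example Chrna9 (log2 -2.70 ± 0.38). Adult replicate 3 stood apart: the mean of the hair cell list was 7.24, 7.39 and 8.44 (log2) in adult replicates 1, 2 and 3, against 9.07, 8.82 and 8.77 at P21 and 8.29, 8.2 and 7.95 at P14. Without it the adjusted p of the list was 3.72e-07. Supporting and epithelial genes fell in 9 of 14 cases, with 1 up (the same counts adjusted over the list alone; camera adjusted p = 0.00059, 0.447 with an estimated correlation). Tectb fell (log2 -2.97 ± 0.24), while Lgr5, a marker of supporting cells, rose (log2 0.56 ± 0.13). Cochlear fibrocyte genes fell in 4 of 7 cases (5 adjusted over the list alone; camera adjusted p = 0.046, 0.456 with an estimated correlation), among them Otos (log2 -1.25 ± 0.24). For the fibrocyte list the adjusted p was 0.0835 without P21 replicate 1, 0.0625 without P21 replicate 2, 0.0717 without adult replicate 1 and 0.0572 without adult replicate 3. It was 0.124 with quantile normalization and ranged from 0.0077 to 0.456 over the alternatives run. For Lgr5, Otos and the fibrocyte list the adjusted p was 0.185, 0.0722 and 0.193 without the 4 libraries low in Eif2s3y, and over the alternatives run it ranged from 0.000353 to 0.185 (Lgr5) and 2.61e-06 to 0.0722 (Otos). Under the other alternatives run, the adjusted p of these 21 lists lay between 9.68e-09 and 0.193. The adult and P21 libraries did not overlap in 56.1% of genes, against 10% by chance. With only both ages in the fit 5211 genes were called, and 3987 without the 4 libraries low in Eif2s3y.

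**Figure D3:**
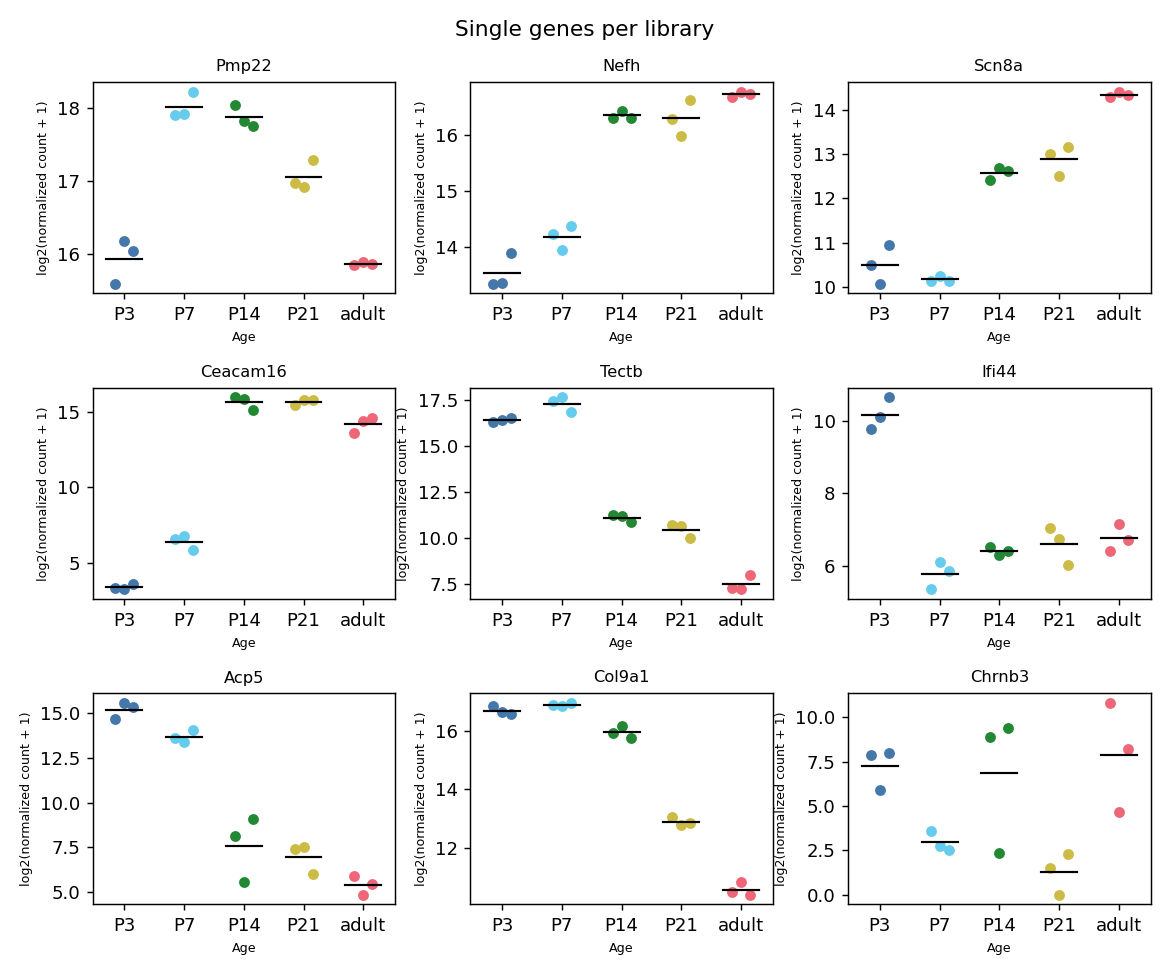
Log2(normalized count + 1) of 9 genes (vertical axes) in each library (points), by age (horizontal axes), with black lines at the mean of the 3 libraries of an age. Ceacam16 and Tectb changed in opposite directions between P7 and P14, and Chrnb3 ranged from 24.1 to 1780 normalized counts among the adult libraries.

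Between P3 and the adult, the widest interval, more genes were called than in the other comparisons. Snap25, a synaptic membrane protein (chromosome 2, 136713450 to 136782428), rose 15.7-fold from 7134 ± 1509 to 110727 ± 7508 normalized counts (log2 fold change 3.98 ± 0.14 SE, adjusted p = 7.97e-11, n = 3 per age, limma), and Kcnab2, a potassium channel subunit (chromosome 4, 152390744 to 152477549), 19.5-fold to 33059 ± 1360 (log2 fold change 4.28 ± 0.12 SE, adjusted p = 1.77e-11). Col3a1, a fibrillar collagen (chromosome 1, 45311538 to 45349706), fell 30.7-fold from 124001 ± 19293 to 4092 ± 1104 (log2 fold change -4.94 ± 0.20 SE, adjusted p = 2.37e-10). Pmp22 stood at 63320 ± 12732 and 59504 ± 911 at both ends (log2 fold change -0.07 ± 0.15 SE, adjusted p = 0.697), and the log2 fold change was 0.05 without P3 replicate 2. Here 5751 genes rose and 5744 fell, 5519 of the 11495 by at least 2-fold.

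By the same rule, the 5 genes that rose most were Ceacam16 (10.81 ± 0.29), Klk6, Xist, Slc4a11 (6.93 ± 0.27) and Hapln2, a link protein of nodes (6.81 ± 0.90). Klk6, a protease of oligodendrocytes, was under the floor of 3 reads at P3 (0.949 ± 1.64) and stood at 1168 ± 226 in adults (adjusted p = 6.14e-07). Xist, transcribed from the inactive X chromosome of females, stood at 508, 1110 and 44400 in adult replicates 1, 2 and 3 and between 4.71 and 18.5 at P3 (adjusted p = 0.0147). Its adjusted p ranged from 3.2e-07 to 0.0741 (without adult replicate 3) over the alternatives run. Eif2s3y was at 0 in P14 replicate 1 and P21 replicates 1 and 2 and at 26.7 in adult replicate 3. In the other 11 libraries Eif2s3y was between 1580 and 3370. By these genes adult replicate 3 was female and all P3 libraries were male, so the call of Xist cannot be told apart from sex. The 5 that fell most were Oc90, Mmp13, a collagenase of hypertrophic cartilage (-11.34 ± 0.92), Col10a1 (-10.46 ± 0.89), Acp5 (-9.84 ± 0.69) and Atp6v0d2. Oc90 went from 20726 ± 4563 to 2.58 ± 0.485 and Atp6v0d2 from 2561 ± 645 to 3.22 ± 2.67, both near the floor in adults. Without adult replicate 1 the log2 fold change was -11.99 (Mmp13), and without adult replicate 2 it was -10.51 (Mmp13) and -11.06 (Col10a1).

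Of 29 genes of the node and paranode, 26 rose, 1 fell and 2 were not called (26 and 1 adjusted over the list alone), and the list rose (camera adjusted p = 2.28e-08, 0.482 with an estimated correlation), Scn4b (log2 5.96 ± 0.18). Spiral ganglion neuron genes rose, 21 of 24 (the same number adjusted over the list alone; camera adjusted p = 2.69e-07, 0.429 with an estimated correlation), Nefh (log2 3.20 ± 0.17). Type I neuron subtype genes rose, 10 of 11 (the same number adjusted over the list alone; camera adjusted p = 2.16e-05, 0.429 with an estimated correlation), Calb2 (log2 4.02 ± 0.17). Synaptic genes rose, 17 of 20 with 2 down (the same counts adjusted over the list alone; camera adjusted p = 7e-06, 0.482 with an estimated correlation), Vamp1 (log2 3.66 ± 0.11), and potassium and HCN channel genes, 11 of 20 with 1 down (the same counts adjusted over the list alone; camera adjusted p = 0.0018, 0.529 with an estimated correlation). Respiratory chain genes rose, 25 of 27 (the same number adjusted over the list alone; camera adjusted p = 2.57e-06, 0.529 with an estimated correlation), Sdha (log2 1.23 ± 0.05). Peripheral myelin genes rose as a list, 12 of 20 with 1 down (the same counts adjusted over the list alone; camera adjusted p = 0.0175, 0.7 with an estimated correlation). Gjb1 rose 8.93-fold and Drp2 8.61-fold, and the member that fell was Pmp2 (log2 -5.27 ± 0.42). With quantile normalization this list's camera adjusted p was 0.181.

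All 23 cell-cycle and all 10 osteoclast genes fell, also adjusted over the lists alone. Their camera adjusted p-values were 1.06e-08 and 6.31e-06, against adjusted p = 0.482 and 0.429 with an estimated correlation. Cenpf fell (log2 -5.45 ± 0.39) and Ctsk (log2 -6.58 ± 0.21). Fibroblast and matrix genes fell, 20 of 21 with 1 up (the same counts adjusted over the list alone; camera adjusted p = 4.36e-08, 0.429 with an estimated correlation), as did basement membrane genes, 11 of 15 (the same number adjusted over the list alone; camera adjusted p = 0.000849, 0.616 with an estimated correlation), Nid2 (log2 -3.57 ± 0.22). Osteoblast and osteocyte genes fell, 14 of 15 with 1 up (the same counts adjusted over the list alone; camera adjusted p = 6.34e-06, 0.482 with an estimated correlation), Ifitm5 (log2 -7.08 ± 0.31). Chondrocyte genes fell, 11 of 16 against 2 (the same counts adjusted over the list alone; camera adjusted p = 0.000958, 0.429 with an estimated correlation): Col9a1 fell 71.1-fold, and the cartilage proteins Acan (log2 1.03 ± 0.29) and Ucma (log2 2.89 ± 0.26) rose. Ribosomal protein genes fell, 21 of 22 (the same number adjusted over the list alone; camera adjusted p = 1.06e-08, 0.482 with an estimated correlation), Rplp0 (log2 -2.34 ± 0.08). Macrophage genes fell, 19 of 21 (the same number adjusted over the list alone; camera adjusted p = 2.18e-06, 0.482 with an estimated correlation), Csf1r (log2 -2.27 ± 0.18), and antigen presentation genes, 11 of 14 (the same number adjusted over the list alone; camera adjusted p = 0.00494, 0.7 with an estimated correlation), Psmb9 (log2 -2.95 ± 0.31). Axon growth and guidance genes fell as a list, 18 of 27 against 3 (the same counts adjusted over the list alone; camera adjusted p = 0.00858, 0.588 with an estimated correlation), Gap43 (log2 -3.93 ± 0.41). Erythroid genes fell, 10 of 13 (the same number adjusted over the list alone; camera adjusted p = 0.0175, 0.762 with an estimated correlation), Alas2 (log2 -2.21 ± 0.34).

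The astrocyte, type II neuron, pericyte and smooth muscle, skeletal muscle, and stria vascularis and melanocyte lists were called in none of the 5 comparisons by camera. Their lowest camera adjusted p-values over the 5 were 0.793, 0.278, 0.0594, 0.187 and 0.082. In the stria vascularis and melanocyte list, 8 of 10 genes fell from P3 to the adult, and Dct, a melanocyte enzyme, ranged from 379 to 6750 among the P3 libraries. Under the other alternatives run, the adjusted p of these 18 lists lay between 1.49e-10 and 0.181. Adult and P3 libraries did not overlap in 76.4% of genes, against 10% by chance.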

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

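The tests with edgeR, with TMM scaling and without the 4 libraries low in Eif2s3y were chosen after seeing the data. Over 169 counts of genes, 152 were within 1.5 times the reported count and 17 were not. Of 1668 list tests, 1541 kept direction and call, 127 lost the call and 0 reversed. Of 3800 tests of 190 named results, 3682 stayed on their side of the threshold, 117 lost the call, 31 of them without the libraries low in Eif2s3y, and 1 reversed (Pmp22, adult against P3, log2 fold change -0.24 to 0.05 without each library in turn, 0.05 without P3 replicate 2). Of 106 tests of the lists chosen after seeing the data, 10 lost the call and 0 reversed. Leaving a library out leaves 2 in its age, whose spread is pooled with the other ages, and without the 4 libraries low in Eif2s3y P21 keeps 1 library, which is assumed to vary like the other ages. The cause was not tested for any of the changes below.

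Requiring a log2 fold change of at least 1 left 950 genes (P7 vs P3), 2413 genes (P14 vs P7), 312 genes (P21 vs P14), 1725 genes (adult vs P21) and 5519 genes (adult vs P3) and 4401 over the 5 ages. With only both ages in the fit, 137 genes (P21 vs P14) and 5211 (adult vs P21) were called, fewer than reported. More than reported were called in the others: 3274 higher and 3335 lower (P7 vs P3), 4365 higher and 4406 lower (P14 vs P7) and 6009 higher and 5966 lower (adult vs P3). For P21 vs P14, DESeq2 called 2519. Without the libraries low in Eif2s3y the counts were 754 (P21 vs P14) and 3987 (adult vs P21). A replicate block over P3, P14, P21 and adult gave 645 for P21 vs P14, against 977 in the same 4 ages without it. The block lost no list call of the fit to all 15 libraries, and it kept the cochlear fibrocyte list (adult vs P21), which the same 4 ages without it lost (0.0503). The numbers are not stated to mark a shared litter or batch: libraries of the same number had deviations correlated between -0.23 and 0.32 (5 of 18 pairs over 0.1), and 4 of 12 correlated best with their own number. Without each library in turn, the counts ranged from 3080 to 6349 (P7 vs P3), 6736 to 9171 (P14 vs P7), 631 to 1969 (P21 vs P14), 6778 to 8514 (adult vs P21) and 10650 to 12199 (adult vs P3) and from 13622 to 14471 over the 5 ages.

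With an estimated correlation, camera called 0 lists in each of the 5 comparisons, and 3 (P7 vs P3), 3 (P14 vs P7), 3 (P21 vs P14), 1 (adult vs P21) and 3 (adult vs P3) had an unadjusted p under 0.05. For P7 vs P3 the adjusted p of the lists called was 0.46 (peripheral myelin, antigen presentation, interferon response), 0.586 (cholesterol biosynthesis, osteoclast), 0.805 (axon growth, respiratory chain, fibroblast) and 0.807 (oligodendrocyte, cell cycle, macrophage). For P14 vs P7 the adjusted p of the lists called was 0.306 (type I neuron), 0.446 (spiral ganglion, osteoclast), 0.668 (synaptic), 0.71 (node, potassium channel, cell cycle, respiratory chain, ribosomal protein, fibroblast, endothelial), 0.714 (axon growth) and 0.935 (interferon response). For P21 vs P14 the adjusted p of the lists called was 0.218 (chondrocyte), 0.459 (immature Schwann cell, fibroblast, basement membrane), 0.466 (peripheral myelin), 0.537 (osteoblast), 0.546 (hair cell), 0.669 (type I neuron), 0.762 (macrophage, erythroid), 0.763 (interferon response) and 0.83 (axon growth, cell cycle, respiratory chain, neutrophil). For adult vs P21 the adjusted p of the lists called was 0.447 (node, spiral ganglion, synaptic, potassium channel, cell cycle, cholesterol biosynthesis, ribosomal protein, complement, osteoblast, chondrocyte, erythroid, B lymphoid, hair cell, supporting cell, immediate early), 0.456 (cochlear fibrocyte), 0.531 (peripheral myelin, macrophage, fibroblast, neutrophil) and 0.624 (respiratory chain). For adult vs P3 the adjusted p of the lists called was 0.429 (spiral ganglion, type I neuron, fibroblast, osteoclast, chondrocyte), 0.482 (node, synaptic, cell cycle, ribosomal protein, macrophage, osteoblast), 0.529 (potassium channel, respiratory chain), 0.588 (axon growth), 0.616 (basement membrane), 0.7 (peripheral myelin, antigen presentation) and 0.762 (erythroid).

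Under fry, 6 lists were called for P21 vs P14, and the lists lost had adjusted p-values of 0.055 (axon growth), 0.0683 (cell cycle), 0.0703 (fibroblast), 0.0868 (macrophage) and 0.1 (oligodendrocyte) for P7 vs P3; 0.0627 (hair cell), 0.117 (type I neuron, macrophage), 0.222 (erythroid), 0.223 (axon growth, interferon response), 0.38 (respiratory chain), 0.451 (neutrophil) and 0.485 (cell cycle) for P21 vs P14; 0.0928 (respiratory chain) for adult vs P21. Without the libraries low in Eif2s3y the lost lists had 0.0874 (type I neuron), 0.13 (neutrophil), 0.17 (immature Schwann cell), 0.314 (interferon response), 0.361 (axon growth) and 0.591 (cell cycle) for P21 vs P14; 0.083 (complement), 0.109 (macrophage), 0.16 (neutrophil) and 0.193 (cochlear fibrocyte) for adult vs P21. Quantile normalization gave 0.124 (cochlear fibrocyte) for adult vs P21 and 0.181 (peripheral myelin) for adult vs P3, and the same 4 ages without a block 0.0503 (cochlear fibrocyte) for adult vs P21.

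Without each library in turn, the adjusted p of the lists that lost a call ranged from 3.9e-05 to 0.981 (cell cycle, P21 vs P14), 0.000249 to 0.463 (neutrophil, P21 vs P14), 0.00464 to 0.105 (immature Schwann cell, P21 vs P14), 0.0207 to 0.0968 (type I neuron, P21 vs P14), 0.00337 to 0.352 (axon growth, P21 vs P14), 3.25e-05 to 0.63 (respiratory chain, P21 vs P14), 0.000358 to 0.0502 (fibroblast, adult vs P21) and 0.021 to 0.0835 (cochlear fibrocyte, adult vs P21). Simulated data with 3 libraries per age gave back between 34.3% and 50.7% of changes of 1.5-fold and between 68.7% and 73.1% of 2-fold changes, so smaller changes can be missed at this number of mice, and 3 reads set the floor of detection.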

Other observations

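The gene lists of this part and its tests, other than the counts over other groupings of the libraries, were chosen only after the results had been seen. Of 12 imprinted genes that control growth, 8 fell and 3 rose from P3 to the adult (camera adjusted p = 0.0179, 0.28 with an estimated correlation and 0.0697 without the 4 libraries low in Eif2s3y). H19, a noncoding RNA, went from 165730 ± 19916 normalized counts at P3 to 625 ± 88.6 in adults (limma, log2 fold change -8.05 ± 0.15 SE, adjusted p = 1.22e-12), and Igf2, the growth factor beside it, from 109395 ± 10548 to 18312 ± 5481 (limma, log2 fold change -2.62 ± 0.20 SE, adjusted p = 7.43e-08). Grb10 fell too (log2 -4.03 ± 0.16), while Meg3 rose (log2 1.78 ± 0.25). Camera, adjusted over the 3 lists of this part, called the list lower from P3 to P7 (adjusted p = 2.13e-05, and 0.0381 with an estimated correlation), from P7 to P14 (0.0378 and 0.35), from P14 to P21 (0.00388 and 0.165), and from P3 to the adult. From P7 to P14 its adjusted p was 0.0535 without P14 replicate 1, 0.0808 without P21 replicate 2, 0.0545 without P21 replicate 3 and 0.198 without the 4 libraries low in Eif2s3y, and it ranged from 2.6e-06 to 0.35 over the alternatives run. Without those 4 libraries it was also 0.0735 (P21 against P14). Over the alternatives run for the other comparisons it ranged from 4.63e-07 to 0.0381 (P7 against P3), from 0.00156 to 0.165 (P21 against P14) and from 1.41e-09 to 0.28 (adult against P3).

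Of 17 ionotropic glutamate receptor genes, 12 rose and 0 fell from P21 to the adult (camera adjusted p = 0.000126, and 0.492 with an estimated correlation, the range over the alternatives run being 2.24e-05 to 0.492). Gria3 rose to 6620 ± 769 normalized counts (log2 0.61 ± 0.10) and Grin1, the subunit shared by NMDA receptors, to 12340 ± 771 (log2 0.88 ± 0.20). For Gria3 and Grin1 the adjusted p was 0.0646 and 0.19 without the 4 libraries low in Eif2s3y, and over the alternatives run it ranged from 7.13e-07 to 0.0646 (Gria3) and 0.00028 to 0.19 (Grin1). From P7 to P14, 6 rose and 6 fell (camera adjusted p = 0.998). Of 17 genes of neurotrophic factors and their receptors, 4 of them in another list, 7 rose and 3 fell from P3 to the adult, and camera called the list in none of the 5 comparisons (lowest adjusted p 0.359). The receptor genes Ntrk2 (log2 1.45 ± 0.19) and Ngfr (log2 1.85 ± 0.21) rose, and so did Cntf, a factor made by Schwann cells (log2 3.02 ± 0.14), while Ntf3 fell (log2 -3.65 ± 0.24).

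Over the 5 ages, 1 of 50 groupings of the 15 libraries, the real one, gave as many as 14274 genes, and the highest of the others gave 2910, so a grouping by chance can be excluded. For each pair of ages the 10 splits of 6 libraries are too few for a share under 0.05. The real splits gave 4703 (P7 against P3), 8048 (P14 against P7), 1553 (P21 against P14), 8266 (adult against P21) and 11495 genes (adult against P3), and the highest other splits 0, 0, 4, 1 and 0. The p-values of the limma and camera tests measure differences between these libraries against the spread among mice of one age, and do not say what made the ages differ.

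From P3 to P7 all 14 antigen presentation and 14 of 15 interferon response genes fell (camera adjusted p = 2.7e-11 and 2.69e-13, 0.46 for both with an estimated correlation). A larger share of macrophages at P3 was argued against: the macrophage list had a median change of -0.51 on the log2 scale (lower quartile -0.87, Csf1r 11267 ± 2255 to 5908 ± 743 normalized counts), while the antigen presentation list had -2.46 (upper quartile -1.47). T and natural killer cells as carriers of these transcripts were argued against as well: 11 of 13 markers were in the table, 0 of them in another list, and their median at P3 was 8.22, against 959 for antigen presentation. Yet the means of several were lower at P7 than at P3 (Cd4, also made by macrophages, 287 to 199, Cd2 53.5 to 21.5, Gzma 39.9 to 2.75, Gzmb 9.28 to 0.323, Nkg7 8.22 to 1.24) while Cd8a (3.09 to 9.87) and Ccl5 (11.5 to 16.8) were higher at P7, and a few such cells acting on others were not tested. Scaling was argued against, since the median change of the interferon list was at most -2.54 with quantile normalization and TMM scaling. A litter or library batch shared by the P3 libraries cannot be told apart from age. The lowest P3 library lay 1.77 above the highest P7 library in the mean of the interferon list, and all P3 mice share their age. An exposure shared by the P3 mice and a change with age, which was not tested apart, both stay open. The interferon mean was lowest at P7 (6.98 to 7.18) and stood between 8.52 and 8.98 in adults, against 8.95 to 10.25 at P3. Camera did not call this list from P3 to the adult. A batch or exposure of the P7 libraries stays open as well and was not tested.

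At P14, P21 and in adults, the mean of the cell-cycle list differed between libraries of one age (8.25, 7.02 and 7.65 in P14 replicates 1, 2 and 3, 8.72, 7.78 and 7.33 at P21 and 6.31, 6.33 and 5.97 in adults, log2). A candidate explanation for these ages is marrow-derived cells in some dissections, since within these ages the cell-cycle mean rose with the mean of the erythroid, neutrophil and B lymphoid lists (r 0.947, rho 0.95, exact permutation p = 0.00926 for both, n = 9, 0.0428 and 0.0243 adjusted over 7 relations, r 0.89 without the 2 farthest libraries). Over all 5 ages the relation was weaker (r 0.807, rho 0.65, permutation p = 0.0122 and 0.0543, n = 15, 0.0428 and 0.076 adjusted, r 0.631 without the 2 farthest). At P7 the erythroid mean was 6.9, 7.09 and 8.35 and the neutrophil mean 5.09, 4.99 and 6.51 in replicates 4, 5 and 6, yet the cell-cycle mean was 9.22, 9.15 and 9.15. At P3 the erythroid mean ranged from 6.75 to 8.23 and the cell-cycle mean only from 9.96 to 10.05. The lists share 0 genes with the cell-cycle list, and the most abundant marrow genes at P21 were Hba-a1 at 13585 ± 6544, Hba-a2 at 11309 ± 5084, Hbb-bs at 7698 ± 2955 and S100a9 at 2706 ± 2477 normalized counts. Fewer marrow-derived cells were argued against as the whole source of the fall from P7 to P14: P14 replicate 1 had higher erythroid, neutrophil and B lymphoid means (8.99, 8.53 and 6.66) than any P7 library (up to 8.35, 6.51 and 5.43), yet a lower cell-cycle mean. That library carried the marrow rise: the 38 marrow genes had a median change of 0.69 (lower quartile 0.29) with it and 0.069 (-0.566) without it, and the cell-cycle genes one of -1.4 and -1.76. A change in dividing cells of the nerve with age stays open for that fall and was not tested. From P21 to the adult, all 13 erythroid, 11 of 12 B lymphoid and 10 of 13 neutrophil genes fell along with 20 of 23 cell-cycle genes. Fewer marrow-derived cells in the adult dissections therefore stay open for this later fall, which was not tested.

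A set of 12 genes led by Chrnb3, 1 of them in a fixed list, differed between libraries of one age (within-age r with Chrnb3 above 0.9, among 316 genes with a within-age SD above 1 on the log2 scale); its mean was 7.02, 2.48 and 7.65 in P14 replicates 1, 2 and 3 and 9.07, 4.43 and 6.7 in adult replicates 1, 2 and 3. A larger share of all neurons was argued against at P14 and in adults, where the spiral ganglion neuron list spanned 0.12 and 0.07 on the log2 scale and the set 5.18 and 4.64. At P3 it stays open, since the spiral ganglion means (11.53, 11.17 and 11.78 in replicates 1, 2 and 3) had the order of the set (6.92, 5.13 and 7.06). The same holds at P7 (11.59, 11.54 and 11.46 in replicates 4, 5 and 6, against 4.12, 3.89 and 3.68). For P21, where the list spanned 0.19 and the set 1.04, nothing is concluded. Within ages the set also moved with other neuronal lists, less its own members: potassium and HCN channels (r 0.717, rho 0.779, permutation p = 0.0199 and 0.00913, 0.0441 and 0.0243 adjusted, r 0.747 without the 2 farthest) and synaptic genes (r 0.637, rho 0.732, permutation p = 0.0252 and 0.0104, 0.0441 and 0.0243 adjusted, r 0.737 without the 2 farthest), but not past the threshold with the spiral ganglion list (r 0.34, rho 0.546, permutation p = 0.0966 and 0.0518, 0.135 and 0.076 adjusted, r 0.524 without the 2 farthest). The channel and synaptic lists spanned 0.47 and 0.22 at P14 and 0.82 and 0.45 in adults. Central nervous tissue with its glia stays open (r 0.225, rho 0.2, permutation p = 0.689 and 0.578, n = 15, 0.689 and 0.578 adjusted, r 0.255 without the 2 farthest libraries), the most abundant of its markers being Gfap at 10397 ± 12057 and Cldn11 at 11652 ± 7570 at P14. Inhibitory neurons of the brainstem or cerebellum could contribute too (7 markers, r 0.574, rho 0.543, permutation p = 0.134 and 0.123, 0.156 and 0.143 adjusted, r 0.548 without the 2 farthest). In P14 replicates 1, 2 and 3, Calb1, also made in the cochlea, stood at 2160, 602 and 2870. Yet Slc32a1 was at 0, 0 and 50.4 and Slc6a5 at 0, 0 and 10.7 there. The labels state no difference between mice of one age, so nothing beyond these 3 explanations was tested.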
